A study of Caenorhabditis elegans with 3 samples.

How the data were processed

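Poly(A) RNA of Caenorhabditis elegans embryos was sequenced from wild type, the 8rex deletion and the DCC mutant, with 5, 5 and 3 replicates per the labels. Per the labels' protocols, worms were grown on HT115 bacteria for RNAi feeding, embryos were isolated by bleaching, RNA was extracted with TRIzol, poly(A) RNA was purified and fragmented, and NEXTflex adaptors were ligated to the cDNA. Mixed-stage embryos, mostly before the comma stage, came from gravid adults. Older embryos came from young adults bleached 68 to 70 hours after plating of the first larval stage, and were left to develop at 20 °C for 7 to 8 hours, until most had reached the 3-fold stage. The genotypes of a replicate were grown and collected in parallel.

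Per the submitters' processing notes, the tools cutadapt 1.2.1, TopHat2 2.1.1 and Cufflinks 2.2.1 and the genome build ce11 were used; the role and settings of each, the annotation and whether strand was used are not given in the sources used here. The authors deposited a single table with 40669 loci. Per the file headers it holds FPKM (fragments per kilobase of transcript, scaled to library size), 1 value per genotype, so the authors had combined the replicates before deposit; how libraries were scaled and weighted is not given in the sources used here. The deposited log2 fold change of each mutant over wild type equalled the log2 ratio of the deposited FPKM within 5.2e-05 wherever both values were above 0, and has no pseudocount. Where exactly 1 of the 2 values was 0 it was infinite at 3953 of 3960 loci for the 8rex deletion and 4225 of 4232 loci for the DCC mutant; the other 7 in each comparison were deposited as 0, which is not a ratio and was not used as one. The authors' p-value and q-value stand beside each fold change, per the file headers; the test is not named there. The smallest deposited p-value was 5e-05, and loci with a p of 1 were taken as not tested. The chromosome position per row is the start of the locus as the authors deposited it, counted from 0.

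A locus can hold several genes that overlap or lie close together, and its FPKM then covers all of them; this was so for 1673 of the 15628 loci used (10.7%). Without stated strand information, reads of overlapping genes cannot be told apart. Rows with no gene identifier (242, or 0.595%) were left out of all comparisons. Of 46148 gene identifiers, 45923 (99.5%) were found in the Ensembl release 115 annotation of the same assembly, which gave symbols, coordinates and gene types; all 35672 single-gene rows found there lay on the chromosome that the annotation gives. Depth per library is unknown. The FPKM columns summed to 913501 in wild type, 932664 in the 8rex deletion and 928618 in the DCC mutant. An exact 0 in this table can be a failed estimate: 106 loci were at 0 in wild type while both other genotypes had at least 10 FPKM, among them widely used genes such as cyn-5 (0, 1297 and 1214 FPKM in wild type, 8rex deletion and DCC mutant) and rpa-1 (0, 249 and 131 FPKM). The corresponding numbers were 83 loci in the 8rex deletion and 218 in the DCC mutant. Such a locus is therefore described only as listed at 0.

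The design written before the data were examined called for linear models over replicates with embryo stage as a covariate. The table has no replicate values, so its stated fallback was used: no test was made here, and the authors' p and q were described. Loci with a mean of at least 1 FPKM over the 3 genotypes were kept, and differences were taken as log2(FPKM + 1). For each comparison, the median over X-linked loci minus the median over autosomal loci was set against 10000 random autosomal lists with the same number of loci in each of 20 bins of mean FPKM. For 27 gene lists fixed before the data were examined, the median over members was set against 10000 random lists of the same size matched in 10 bins of mean FPKM, among the 11146 loci with exactly 1 protein-coding gene. X-linked windows of 1 Mb were set against X-linked random lists in the same way. A percentile below 2.5 or above 97.5 is called outside the range. These percentiles describe these pooled values and are not p-values, since genes are not replicates. Counts adjusted over a list alone apply the Benjamini-Hochberg method to the authors' p. Intervals of shares are exact binomial 95% intervals over loci and cover counting error only.

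The steps were tested on simulated data made from the wild-type values with log2 noise of SD 0.4. For X against autosomes over 15628 loci, a simulated shift of 0 was returned as 0.00, and a shift of 0.5 as 0.34, since the pseudocount and loci at 0 damp the score. For lists of 20 genes among 11273 loci, 8.0% of unshifted lists fell outside the 95% range, 99.0% of lists shifted by 0.5 and 100% of lists shifted by 1. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

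The genes named were chosen by a rule written before the data were examined. It takes sdc-2, the other subunit genes of the complex, xol-1 and her-1. It also takes the 8 highest and the 8 lowest fold changes per comparison among significant genes outside the lowest of 4 equal groups by level, up to 4 members of lowest p from each list that stood apart or had at least 3 called members, and all called genes of the 8rex deletion if few. As no q was under 0.05, an authors' p under 0.05 replaced it for the fold-change and list parts, and a q under 0.1 for the last part, which was also applied to the DCC mutant; both choices were made after the values were seen. The part of the rule that asks for the same direction in each replicate could not be applied. Alternatives tried were other filters, pseudocounts, centring on the autosomal median, the mean in place of the median, other thresholds, wider windows, loci with a single coding gene, and other matching of random lists.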

Results

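Poly(A) RNA was sequenced from Caenorhabditis elegans embryos of 3 genotypes. The first was wild type (strain N2, 5 replicates in the labels). The second, called 8rex deletion here (strain TY5827, 5 replicates), lacks 8 rex sites on the X chromosome; rex sites are the DNA elements at which the dosage compensation complex is recruited to X. The third, called DCC mutant here (strain TY0810, 3 replicates), carries a mutation in sdc-2 and was also fed bacteria expressing sdc-2 RNAi; SDC-2 brings the dosage compensation complex (DCC) to the X chromosomes of XX embryos, where the complex lowers transcription. Wild-type and 8rex deletion worms were fed bacteria with an empty vector. The authors' deposited table held a single FPKM value per genotype and locus, in which the replicates were already combined, so no value below has a standard deviation and no difference has a replicate check other than the authors' own p and q. The number of reads per library is unknown. Of the 40669 loci in the table, 15628 had a gene identifier and a mean of at least 1 FPKM over the 3 genotypes, 2939 of them on X and 12689 on the autosomes. Differences described as log2 below are on the log2(FPKM + 1) scale, which understates the change of low genes, except where a sentence gives the authors' own log2 fold change. Coordinates are from the annotation of the ce11 assembly, 1-based.

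The replicates differed in embryo stage. Wild type and the 8rex deletion each had 2 replicates of mixed-stage embryos and 3 of older embryos, while the DCC mutant had 2 mixed-stage replicates and 1 older replicate. If replicates were weighted equally, older embryos made up 60% of the wild-type value and 33.3% of the DCC mutant value. Every DCC mutant comparison below carries that difference. The 8rex deletion and wild type had equal numbers of replicates per stage. How replicates were weighted is not given, so the pooled values of these 2 genotypes may still differ in stage.

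The target gene was examined first. In the authors' deposited table, sdc-2 (WBGene00004746, protein-coding, X, 11522707 to 11533450) stood at 18 FPKM in wild type, 16 FPKM in the 8rex deletion and 11 FPKM in the DCC mutant, a difference of the DCC mutant from wild type that did not pass the authors' test (p = 0.505). RNAi lowers the message only in part, so a residual level of transcript does not measure the protein. Among the other genes of the complex, the authors' deposited table gave dpy-27 at 115 FPKM in wild type and 107 FPKM in the DCC mutant (p = 0.763), dpy-28 at 29.1 and 28.5 FPKM (p = 0.946), dpy-21 at 70.4 and 63.9 FPKM (p = 0.692) and mix-1 at 66.7 and 71.0 FPKM (p = 0.893). The X-linked subunit gene sdc-1 stood at 24 FPKM in wild type and 40.4 FPKM in the DCC mutant in the authors' deposited table (p = 0.0852). In that table of the authors, dpy-26, capg-1, dpy-30 and sdc-3 shared loci with neighbouring genes, and the DCC mutant p of these loci was 0.989, 0.985, 0.714 and 0.144; dpy-26 also had a locus of its own (p = 0.716). No subunit gene of the 10 stood at a p under 0.05 in the authors' comparison of the 8rex deletion with wild type, and the median of the 7 measured at loci of their own was -0.10 in that comparison (percentile 19.9 among 10000 random lists matched on level) and -0.11 in the DCC mutant (percentile 16).

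The DCC mutant was compared with wild type to show what loss of the complex does to expression of X and of the autosomes. X-linked genes were higher as a group in the DCC mutant and autosomal genes were not. The median log2 difference was 0.46 over the 2939 X-linked loci (interquartile range 0.00 to 0.77) and -0.04 over the 12689 autosomal loci (interquartile range -0.41 to 0.25). X stood 0.50 above the autosomes, or 1.41-fold, whereas random autosomal lists matched on level lay between -0.02 and 0.02 (95% range of 10000 lists). Of X-linked loci, 70.3% were above 0, against 42.8% of autosomal loci, and 39.3% were more than 1.5-fold higher, against 13%. Among loci with a single protein-coding gene and no other gene, X stood 0.60 above the autosomes (1.51-fold; 1782 X-linked and 9055 autosomal loci), and 87.8% of X-linked loci were above 0. By chromosome, the medians were 0.00 on I, -0.02 on II, -0.02 on III, -0.06 on IV, -0.09 on V and 0.46 on X. Whether the shift of X relative to autosomes depends on level is not settled by these values. From the lowest to the highest of 4 equal groups of loci by mean FPKM it was 0.34, 0.39, 0.52 and 0.55, but simulated data with an equal shift of 0.5 at each level gave 0.23, 0.31, 0.41 and 0.52 on the same scale, and without a pseudocount, at loci above 0 FPKM in both genotypes, the order turned round (0.79, 0.66, 0.59 and 0.56); both checks were added after the data were seen.

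**Figure D1:**
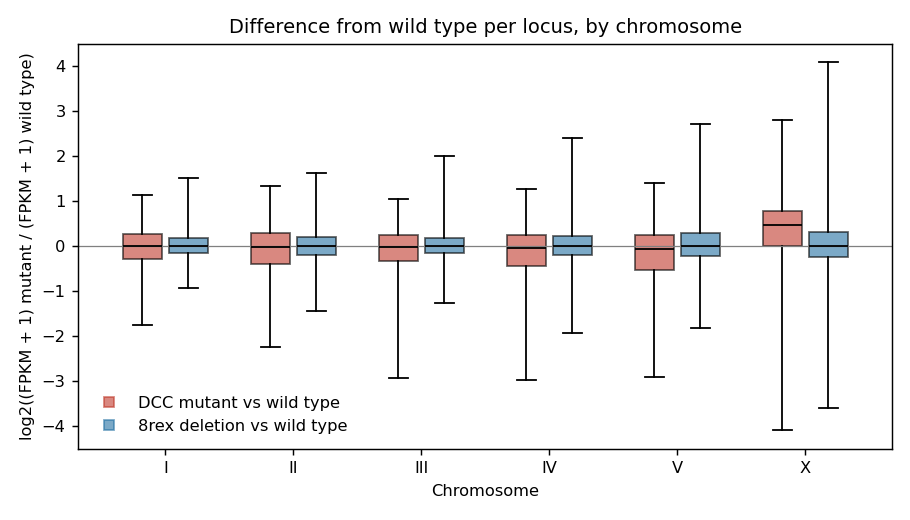
Log2 difference from wild type on the FPKM + 1 scale (vertical axis) for the 15628 loci, by chromosome (horizontal axis), in the DCC mutant (red) and the 8rex deletion (blue). Boxes span the interquartile range with the median as a line and whiskers reach from the 5th to the 95th percentile of loci, not of replicates; the X box of the DCC mutant has its median at 0.46, and that of the 8rex deletion at 0.00.

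Gene by gene, the authors' test called no locus at an adjusted level of 0.05. In the authors' deposited table the smallest q was 0.0632, shared by 7 named loci. An unadjusted p under 0.05 was found at 197 of 9509 tested loci, where 5% of the tests would be 475. That 5% is the chance count only if p-values without a true difference are spread evenly. The median of the authors' p was 0.668, so they ran high and the 197 cannot be read as fewer than chance. Those 197 loci were 132 with a higher value and 65 with a lower value in the DCC mutant. On X, 63 of the 65 such loci were higher, while on the autosomes 69 were higher and 63 lower, according to the authors' p. These were 4.08% of the X-linked tests and 1.67% of the autosomal tests. Adjusted over the X-linked tests alone, 0 loci lay under 0.05. By value, 3224 of the 15628 loci differed at least 2-fold, 1336 higher and 1888 lower in the DCC mutant. On X these were 469 and 364. Of the lower loci 1189 were listed at 0 in the DCC mutant and of the higher loci 541 at 0 in wild type; at loci above 0 in both, 795 were higher and 699 lower, and on X 273 and 60. With no replicate values this count mixes differences of genotype with noise between libraries.

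Of the 7 named loci at the smallest p, 6 had lower values in the DCC mutant and 1, srh-2/C05E4.16, a higher value. The alcohol dehydrogenase gene adh-1 (WBGene00010790, V, 11888248 to 11889650) stood in the authors' deposited table at 84.8 FPKM in wild type and 6.56 FPKM in the DCC mutant (12.9-fold lower, p = 5e-05, q = 0.0632). The flavin monooxygenase gene fmo-2 (WBGene00001477, IV, 10682524 to 10684367) stood at 63.7 and 5.40 FPKM (11.8-fold lower, the authors' p = 5e-05). The lipid-binding protein gene far-3 (WBGene00001387, V, 12996787 to 12997522) stood at 260.3 and 46.4 FPKM (5.61-fold lower, the authors' p = 5e-05). The locus that joins acdh-1, an acyl-CoA dehydrogenase gene, with C55B7.3 (I, 6497436 to 6501410) stood at 248 and 54.8 FPKM (4.52-fold lower, the authors' p = 5e-05). In the 8rex deletion these loci stood at 63.3, 63.4, 296 and 252 FPKM in the authors' table, with p between 0.246 and 0.982. The 3 others at the smallest p were merged loci. The authors' table gave sinh-1/Y57A10A.44 at 118 FPKM in wild type and 5.54 FPKM in the DCC mutant, a locus of 4 genes that includes mob-3 at 856 and 65.1 FPKM, and srh-2/C05E4.16 at 2.47 and 50.5 FPKM. Each of these loci joins coding and non-coding genes, so the share of any 1 gene in its value is not known.

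Among the other loci with the largest differences at an authors' p under 0.05 were 3 merged loci on X. The lgc-58 locus stood in the authors' deposited table at 15.7 FPKM in wild type and 474 FPKM in the DCC mutant (p = 0.0187), lin-14 with its neighbours, which holds a regulator of developmental timing, at 247 and 1849 FPKM (p = 0.0230), and grk-1/F19C6.12 at 55.4 and 471 FPKM (p = 0.0246). Of autosomal loci, the authors' table gave C07E3.3/C07E3.17 at 15.3 and 138 FPKM (p = 0.0171), C51E3.10 at 37.5 and 259.9 FPKM (p = 0.0167), the tRNA splicing gene tsen-34 at 5.67 and 50.6 FPKM (p = 0.0202) and bir-2, a gene of the BIR family, at 4.20 and 38.7 FPKM (p = 0.002). On the lower side, the authors' table gave unc-49/T21C12.12, which holds a GABA receptor gene, at 366 and 29 FPKM (p = 0.0001), C31G12.4/linc-98 at 24.6 and 0.864 FPKM (p = 0.0345), Y57G11C.38 at 37.2 and 1.43 FPKM (p = 0.0149) and C23H5.11 at 53.4 and 3.66 FPKM (p = 0.0262).

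Of 13 measured sex-determination genes, 8 were above 0 and 5 below in the DCC mutant. The gene her-1, which promotes male fate (WBGene00001842, V, 9697015 to 9702035), stood in the authors' deposited table at 48.5 FPKM in wild type, 284 FPKM in the DCC mutant (p = 0.223) and 6.92 FPKM in the 8rex deletion (p = 0.357). The male switch gene xol-1 (X, 8041313 to 8044409) stood at 0.978, 7.41 and 1.84 FPKM in the same order in the authors' table, with p = 0.202 in the DCC mutant and a p of 1 in the 8rex deletion. The X signal gene fox-1, in a locus shared with R04B3.7, was at 87.9 FPKM in wild type and 153 FPKM in the DCC mutant (the authors' p = 0.044), and tra-1, with a non-coding neighbour, at 9.93 and 6.29 FPKM (the authors' p = 0.257). The list had a median of 0.49 (percentile 99.3 among matched random lists). When loci that hold several coding genes were added, its 17 loci had a median of 0.26 at percentile 93.7, inside the random range.

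Genes of oocytes, early embryos and dividing cells were higher as groups in the DCC mutant, whose pool held a smaller share of older replicates. The 27 measured maternal and early-embryo genes had a median log2 difference of 0.82, with 25 above 0 and 8 at an authors' p under 0.05, all higher. The zygotic polarity gene mex-5 stood in the authors' deposited table at 42.4 FPKM in wild type and 126 FPKM in the DCC mutant (p = 0.00505), pos-1 at 93.6 and 239 FPKM (p = 0.00665), mex-6 at 24.8 and 66.8 FPKM (p = 0.0121) and spn-4 at 61.6 and 139.9 FPKM (p = 0.0122). None of the 8 passed when adjusted over the list alone. The 20 germline genes had a median of 0.71 with 2 at an authors' p under 0.05. The authors' table gave prg-1, which encodes a Piwi Argonaute, at 16.54 and 53.9 FPKM (p = 0.0109), meg-3 at 8.03 and 17.7 FPKM (p = 0.0463), syp-1 at 8.98 and 20.2 FPKM (p = 0.0651) and glh-1 at 22.6 and 36.2 FPKM (p = 0.0919). All 21 cell-cycle and replication genes were above 0, with a median of 0.56. The authors' table gave the sliding-clamp gene pcn-1 at 153 and 309 FPKM (p = 0.0274), cyb-2.2 at 11.9 and 29.6 FPKM (p = 0.0364), mcm-2 at 30.5 and 55.9 FPKM (p = 0.0583) and cyb-3 at 274 and 454 FPKM (p = 0.107). The 24 measured histone genes had a median of 0.83 with none at a p under 0.05. Examples in the authors' table were his-68 at 5.82 and 16.7 FPKM (p = 0.133), his-71 at 258 and 380.3 FPKM (p = 0.147), his-32 at 20.7 and 45 FPKM (p = 0.153) and his-61 at 5.49 and 12.59 FPKM (p = 0.208). These 4 lists lay at percentile 100 among 10000 random lists matched on level, and again when the random lists were also matched on their number of X-linked members.

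Genes of detoxification, cuticle collagens, ribosomal proteins and a list of DAF-16 responsive and antioxidant genes were lower as groups in the DCC mutant. The 110 measured cytochrome P450, UDP-glucuronosyltransferase and glutathione S-transferase genes had a median of -0.43, with 80 below 0, 30 above 0 and 4 at an authors' p under 0.05, all lower. The gene cyp-35A2 stood in the authors' deposited table at 19.9 FPKM in wild type and 4.57 FPKM in the DCC mutant (p = 0.00965), gst-5 at 116.6 and 25.9 FPKM (p = 0.0132), the locus of ugt-22 and 3 piRNA genes at 39.5 and 8.61 FPKM (p = 0.0194) and cyp-35C1 at 46.9 and 15.9 FPKM (p = 0.0208). The 20 genes listed as responsive to the transcription factor DAF-16 or as antioxidant had a median of -0.85, with 13 below 0. In this list the members did not go one way, and 3 of its 15 tested genes were under 0.05 when adjusted over the list alone. These were the glyoxylate-cycle gene icl-1, at 406 and 202 FPKM in the authors' deposited table (p = 0.0032), the fatty-acid desaturase gene fat-6, at 35.0 and 9.07 FPKM (p = 0.00585), and the small heat-shock protein gene sip-1, which was higher at 335 and 808 FPKM (p = 0.0038). The authors' table also gave dod-3 at 21.5 and 4.62 FPKM (p = 0.0299). The 86 cuticle collagen genes had a median of -0.28, with 65 below 0 and 1 at an authors' p under 0.05. That gene was col-125, at 122.6 and 59.8 FPKM in the authors' deposited table (p = 0.0221), followed there by col-54 at 19.7 and 8.5 FPKM (p = 0.059), col-130 at 21.1 and 9.29 FPKM (p = 0.0922) and col-105 at 17.9 and 10.4 FPKM (p = 0.211). The 49 ribosomal protein genes had a median of -0.23, with 47 below 0 and none at a p under 0.05. The authors' table gave rps-9 at 1697 and 1350.0 FPKM (p = 0.312) and rpl-39 at 4128 and 3100.3 FPKM (p = 0.349). These 4 lists lay at percentile 0 among the random lists. The 39 hedgehog-related genes had a median of -0.17 (percentile 1.41), a call that ended without the filter on low values (54 genes, median -0.09, percentile 15.5). Their lowest authors' p belonged to grl-4, which was higher at 26.3 and 91.6 FPKM (p = 0.00315 in the authors' deposited table), followed by grl-16 at 230.5 and 146 FPKM (the authors' p = 0.105), wrt-4 at 26.7 and 44.1 FPKM (p = 0.135) and grd-1 at 15.2 and 24.3 FPKM (p = 0.161), so 3 of these 4 were higher.

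The remaining lists lay within the range of random lists in the DCC mutant. Their medians were 0.38 for RNA interference, 0.36 for other condensin and cohesin genes, 0.30 for apoptosis, 0.16 for the unfolded protein response, 0.12 for neuropeptides, 0.12 for pharynx, 0.10 for neurons and 0.04 for body wall muscle. They were 0.02 for insulin pathway and longevity genes, 0.02 for Wnt and Notch signalling, -0.04 for heat shock and chaperones, -0.09 for intestine, -0.09 for innate immunity, -0.11 for epidermis and seam and -0.25 for sperm genes. In the pharynx list, the X-linked myosin gene myo-2 (X, 12468061 to 12475348) stood at 36.2 FPKM in wild type and 93.1 FPKM in the DCC mutant in the authors' deposited table (p = 0.0015), under 0.05 when adjusted over the list alone. When random lists were matched on their X-linked members as well, the 15 RNA interference genes moved outside the range (percentile 99.0). Further settings were also chosen after the data were seen. With loci of several coding genes added, RNA interference (23 loci, percentile 98.97) and intestine (26 loci, median -0.16, percentile 2.33) lay outside it. Neuropeptides did so with the stricter filter (68 genes, median 0.28, percentile 99.6) and sperm genes without a filter (40 genes, median -0.40, percentile 0.53). None of the 6 vitellogenin genes reached a mean of 1 FPKM at a locus with a single coding gene. In all, 10 of the 26 lists with at least 3 measured members lay outside the 95% range of random lists, 5 above and 5 below, where 1.3 would be expected by chance and 2.08 at the rate seen for unshifted simulated lists. Those 2 reference counts hold for genes that vary independently. Members of a list can vary together, so the counts may be too low. In the authors' table no list member had a q under 0.05.

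**Figure D2:**
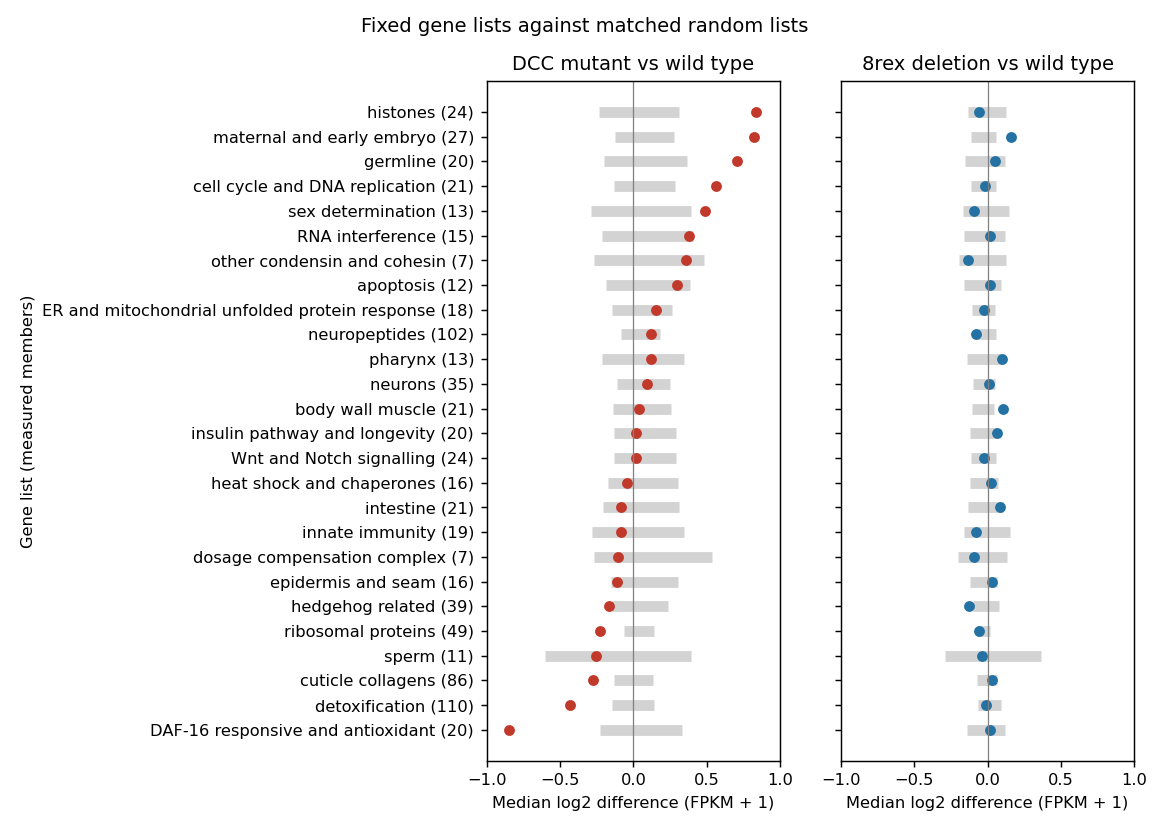
Median log2 difference from wild type on the FPKM + 1 scale (horizontal axis) of each gene list fixed before the data were examined (vertical axis, with the number of measured members), in the DCC mutant (red) and the 8rex deletion (blue). Grey bars span the 95% range of medians of 10000 random lists matched on level; in the DCC mutant 10 of 26 lists lie outside their bars, from -0.85 to 0.83, and in the 8rex deletion 6 do, from -0.13 to 0.16.

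The 8rex deletion was compared with wild type to ask whether loss of the 8 recruitment sites changes expression of X. X-linked genes as a group were at nearly the wild-type level. The median log2 difference was 0.00 over X-linked loci (interquartile range -0.25 to 0.29) and 0.00 over autosomal loci (interquartile range -0.20 to 0.20). X minus autosomes was 0.0022, and matched random autosomal lists lay between -0.0079 and 0.0037 (percentile 45.1). Above 0 were 46.0% of X-linked loci and 48.0% of autosomal loci. The sign of this difference depended on the loci taken. At the 1782 X-linked and 9055 autosomal loci with a single protein-coding gene it was -0.03 (0.981-fold, random lists between -0.01 and 0.01), with 43.4% of X-linked and 48.0% of autosomal loci above 0. With 1 value per genotype, no replicate spread is available against which to set a difference of this size.

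By the authors' test, no locus differed between the 8rex deletion and wild type at an adjusted level of 0.05. The smallest q in the authors' deposited table was 0.0632, at 6 loci, and 43 of 9378 tested loci had an unadjusted p under 0.05, where 5% would be 469. The median of the authors' p was 0.813, so that 5% is not a chance count here either. Of the 43, 27 were higher and 16 lower in the 8rex deletion, and 5 lay on X, 3 of them higher. Of the 43 loci, 14 held a single protein-coding gene and no other gene (29, or 67.4%, did not, with an exact binomial 95% interval of 51.5% to 80.9%), whereas loci of the other kinds made up 20.8% of the tests. By value, 2561 of the 15628 loci differed at least 2-fold, 1462 higher and 1099 lower. Of the higher loci 968 were listed at 0 in wild type and of the lower loci 778 at 0 in the 8rex deletion. At loci above 0 in both, 494 were higher and 321 lower, and on X 97 and 75. With zeros included, 417 X-linked loci were higher, 320 of them listed at 0 in wild type. Lower were 306 X-linked loci, 231 of them listed at 0 in the 8rex deletion.

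The 6 loci at the smallest q included the intestinal GATA factor genes and a long non-coding RNA on X. In the authors' deposited table the joint locus of elt-2 and elt-4 (X, 10475527 to 10483441) stood at 35.3 FPKM in wild type, 202 FPKM in the 8rex deletion (5.72-fold higher, p = 5e-05, q = 0.0632) and 40.8 FPKM in the DCC mutant. The non-coding locus tts-1/F09E10.14 (X, 1504131 to 1504998) stood at 44.2, 219.9 and 29.3 FPKM in the same order in that table of the authors (4.97-fold higher in the 8rex deletion, p = 5e-05). These were the 2 loci under 0.05 when the 1466 X-linked tests were adjusted over the list alone (adjusted p = 0.0367 from the authors' p). On autosomes, the authors' table gave the coding gene Y54G11A.14 (WBGene00013221, II, 14318158 to 14321018) at 5.73 FPKM in wild type and 61.8 FPKM in the 8rex deletion, siah-1/Y37E11AR.9 (IV, 3744048 to 3747610) at 109 and 273 FPKM, Y75B8A.13/Y75B8A.52 (III, 12203756 to 12215696) at 15.9 and 189 FPKM and sinh-1/Y57A10A.44 (II, 12228305 to 12238242) at 118 and 8.52 FPKM, each with p = 5e-05. The locus sinh-1/Y57A10A.44 was also at the smallest p in the authors' DCC mutant comparison, at 5.54 FPKM, and both comparisons share the same wild-type libraries. Of these 6 loci, Y54G11A.14 alone held a single gene.

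Among loci at an authors' p under 0.05, those with the largest fold changes were taken on each side. On the higher side, the authors' deposited table gave C33A12.19 at 3.47 FPKM in wild type and 149 FPKM in the 8rex deletion (p = 0.0319), the insulin-like peptide gene ins-29 at 0.741 and 10.9 FPKM (p = 0.0257), C37A5.11 at 2.42 and 28.3 FPKM (p = 0.029), C44B12.9 at 0.990 and 10.3 FPKM (p = 0.0308) and the non-coding gene B0379.10 at 9.90 and 137.7 FPKM (p = 0.0262). The locus Y37E11B.16 with a neighbouring non-coding gene stood there at 5.74 and 148 FPKM (the authors' p = 0.0201). On the lower side, the authors' table gave the TRPV channel gene ocr-1 at 89.9 and 0.676 FPKM (p = 0.0155), with 255 FPKM in the DCC mutant (p = 0.513), the antisense non-coding gene anr-1 at 7.69 and 0.201 FPKM (p = 0.02) and unc-49/T21C12.12 at 366 and 61.3 FPKM (p = 0.0014). It also gave D2096.9 at 11.2 and 1.19 FPKM (the authors' p = 0.0256), the X-linked non-coding gene K02G10.14 at 126.6 and 14.6 FPKM (p = 0.0383), K07H8.12 at 16 and 3.21 FPKM (p = 0.029) and alg-5 with its neighbours at 39.8 and 8.51 FPKM (p = 0.0221).

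Gene groups differed little between the 8rex deletion and wild type. The 27 maternal and early-embryo genes had a median of 0.16 (percentile 99.99, 21 above 0), the 21 body wall muscle genes 0.10 (percentile 99.9), the 13 pharynx genes 0.10 (percentile 98.1) and the 20 insulin pathway and longevity genes 0.06 (percentile 97.8). The 39 hedgehog-related genes had a median of -0.13 (percentile 0.65) and the 102 neuropeptide genes -0.08 (percentile 1.78). These 6 lists of 26 lay outside the random range, where 1.3 would be expected by chance and 2.08 at the rate seen for unshifted simulated lists. Both reference counts treat genes as independent, whereas members of a list can vary together, so they may be too low. The calls of 4 of the 6 lists were lost under other settings, all chosen after the data were seen. The hedgehog-related and pharynx lists were inside the range with the stricter filter (percentiles 26.8 and 95.3) and the longevity list at its upper edge, and all 3 were inside without a filter (62.2, 96.8 and 97.2). The pharynx list was also inside with a pseudocount of 5 (95.3). With loci of several coding genes added, the longevity list had a median of 0.03 (percentile 92.5) and neuropeptides -0.06 (percentile 3.63), both inside. Across the 6, the neuropeptide gene ins-29 was the only member with an authors' p under 0.05. In the authors' deposited table, other members with the lowest p were mex-1 at 16.08 FPKM in wild type and 25.5 FPKM in the 8rex deletion (p = 0.252), cpg-2 at 26.8 and 37.8 FPKM (p = 0.264), cey-3 at 39.8 and 52.9 FPKM (p = 0.442) and par-1 with a neighbour at 183 and 216 FPKM (p = 0.522). Of hedgehog-related genes, the authors' table gave grd-12 at 7.41 and 17.9 FPKM (p = 0.26), grl-23 at 3.95 and 9.01 FPKM (p = 0.324), grl-4 at 26.3 and 36.6 FPKM (p = 0.366) and wrt-8 at 6.67 and 4.54 FPKM (p = 0.39), so 3 of these 4 went against the median of the list. Of neuropeptide genes the authors' table gave, after ins-29, flp-5 at 9.17 and 19.1 FPKM (p = 0.194), nlp-7 at 28.6 and 16 FPKM (p = 0.233) and ins-6 at 7.70 and 16.13 FPKM (p = 0.258), so 3 of the 4 with the lowest p were higher although the median was below 0. Muscle genes with the lowest authors' p were unc-22 with a non-coding neighbour, at 28.9 and 20.5 FPKM in the authors' deposited table (p = 0.273), unc-89 at 38.8 and 48.9 FPKM (p = 0.371), dim-1 at 319 and 367 FPKM (p = 0.516) and unc-68 at 58.6 and 66.4 FPKM (p = 0.608). Among pharynx genes the authors' table gave phat-2 at 85.5 and 63.8 FPKM (p = 0.324), tnt-4 at 140 and 169 FPKM (p = 0.419), myo-2 at 36.2 and 42.8 FPKM (p = 0.501) and pha-4 at 116 and 99.6 FPKM (p = 0.525).

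Lifespan regulators were among the lists because the series title names lifespan. Of the 20 measured insulin pathway and longevity genes, 13 were above 0 and 7 below in the 8rex deletion, with none at an authors' p under 0.05. In the authors' deposited table, clk-1, a gene of ubiquinone synthesis, stood at 41.1 FPKM in wild type and 30.9 FPKM in the 8rex deletion (p = 0.398), the sirtuin gene sir-2.1 at 53.7 and 42.2 FPKM (p = 0.4) and the X-linked nuclear receptor gene daf-12 at 11.1 and 14.5 FPKM (p = 0.407). The 20 genes listed as DAF-16 responsive or antioxidant had a median of 0.01 in the 8rex deletion, the 16 heat-shock and chaperone genes 0.02 and the 110 detoxification genes -0.01, inside the random ranges. Also inside the ranges were intestine at 0.09, germline at 0.05, epidermis and seam at 0.03, cuticle collagens at 0.03, RNA interference at 0.02, apoptosis at 0.01 and neurons at 0.01. So were cell cycle and replication at -0.02, Wnt and Notch signalling at -0.02, the unfolded protein response at -0.03, sperm at -0.04, ribosomal proteins at -0.06, histones at -0.06, innate immunity at -0.08, sex determination at -0.10 and other condensin and cohesin genes at -0.13. With loci of several coding genes added, intestine moved outside the range (26 loci, median 0.10, percentile 98.7), with the elt-2/elt-4 locus under 0.05 when adjusted over the list alone, and so did ribosomal proteins (77 loci, median -0.06, percentile 0.77).

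Because the deleted sites lie along X, X-linked loci were also taken in 18 windows of 1 Mb; the positions of the sites were not given in the labels and were not used here. In the 8rex deletion the window medians ran from -0.08 at 8 to 9 Mb (154 loci, percentile 0.86 among X-linked lists of the same size and level) to 0.05 at 16 to 17 Mb (148 loci, percentile 99.4). These 2 windows lay outside the random range, where 0.9 of 18 would be expected if loci varied independently. None of the 9 windows of 2 Mb did. The 5 X-linked loci with an authors' p under 0.05 fell in 5 different windows.

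**Figure D3:**
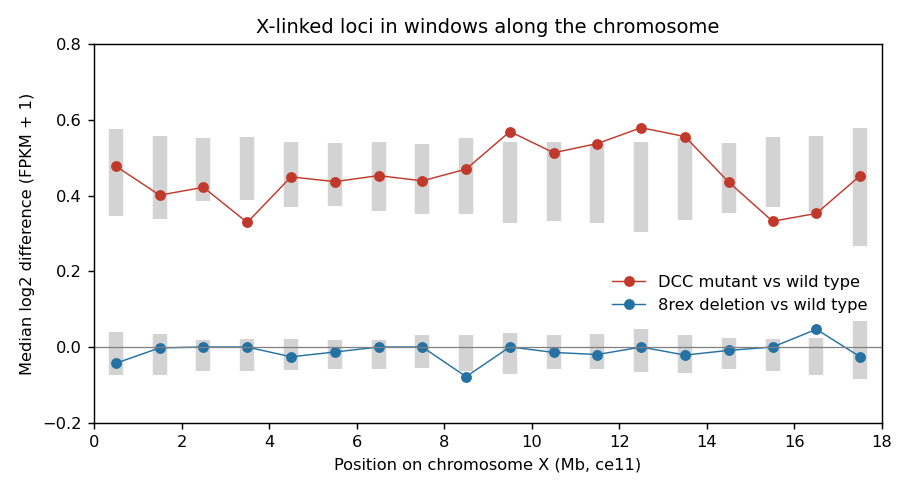
Median log2 difference from wild type on the FPKM + 1 scale (vertical axis) of X-linked loci in 18 windows of 1 Mb along the chromosome (horizontal axis, Mb), in the DCC mutant (red) and the 8rex deletion (blue). Grey bars span the 95% range of random X-linked lists of the same size and level; the DCC mutant medians run from 0.33 to 0.58 and the 8rex deletion medians from -0.08 to 0.05.

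The DCC mutant was also set against the 8rex deletion directly. X-linked genes were higher in the DCC mutant, with a median log2 difference of 0.51 on X (interquartile range 0.00 to 0.81) and -0.04 on the autosomes (interquartile range -0.46 to 0.27). X minus autosomes was 0.55, or 1.47-fold, with matched random lists between -0.02 and 0.02, and 69.6% of X-linked loci were above 0 against 43.3% of autosomal loci. At least 2-fold higher in the DCC mutant were 1349 loci and at least 2-fold lower 2270, and on X 498 and 482. The DCC mutant column had fewer loci above 0 (16405, against 18289 in the 8rex deletion and 18121 in wild type), and 1356 of the lower loci were listed at 0 in the DCC mutant, against 493 of the higher loci at 0 in the 8rex deletion. At loci above 0 in both, 856 were higher and 914 lower, and on X 324 and 108. The table used here has no p for this comparison, and the stage composition of the groups differs in it as it does between the DCC mutant and wild type.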

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

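The tests of late-tissue lists against random autosomal lists, of the share of X among low p, of loci other than single coding genes among autosomal low p and of the smallest p were chosen after the result was seen; the others were written before their result was seen.

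A signal lay among the rows without a gene identifier, which no comparison used. In the authors' deposited table a locus on X that starts at 14403932 was listed at 0 in wild type, at 0 in the 8rex deletion and at 1172 FPKM in the DCC mutant (p = 5e-05), with no annotated gene at that start; an exact 0 in this table can be a failed estimate.

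In the DCC mutant, genes of oocytes, early embryos and cell division were higher as lists, and collagen, detoxification and, with the filter on low values, hedgehog-related genes lower. In the 8rex deletion, which had as many replicates of each stage as wild type, the maternal and early-embryo list was higher as well (median 0.16, percentile 99.99, against 0.82 in the DCC mutant) and the hedgehog-related list lower (-0.13, percentile 0.65, against -0.17), though the second of these calls was lost in the 8rex deletion with the stricter filter (percentile 26.8) and without a filter (62.2). The other lists of these kinds did not follow in the 8rex deletion: cell cycle -0.02 (percentile 59.5), histones -0.06 (18), germline 0.05 (80.5), collagens 0.03 (84.4) and detoxification -0.01 (31.5) lay inside the random range. Ribosomal proteins, also lower in the DCC mutant, had 42 of 49 genes below 0 in the 8rex deletion (percentile 6.32, inside). With loci of several coding genes added they lay outside (77 loci, percentile 0.77). Both comparisons share the wild-type libraries. The smaller share of older replicates in the DCC mutant pool may account for part of this, but beyond the collagen and hedgehog-related lists that prompted the idea the values did not decide it: 134 autosomal members of the 5 other lists of late-forming tissues had a median of -0.05, at percentile 29 among matched random autosomal lists. The X shift was also present within the late lists. There, 77 X-linked members of all 7 late lists stood 0.73 above the autosomal members, where relabelling X at random gave -0.12 to 0.13. That difference met the outcome set in advance against the stage mix as the whole cause of the X shift. The autosomal side of that difference holds the collagen and hedgehog-related genes that prompted the idea, but the X-linked members themselves had a median of 0.58. If X-linked genes as a class were higher in younger embryos, the stage mix would give the same values. Despite the outcome above, the stage mix is therefore not excluded as a cause of the X shift. With equal weights the stage mix could raise a gene by at most 0.74, and 16 of 27 maternal genes exceeded that on the authors' log2 scale, but the weights are assumed and this excludes nothing. A slower development of DCC mutant embryos, which is a property of the genotype, stays open and was not tested, since stage and genotype differ together in these pools.

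In the 8rex deletion, 29 of the 43 loci with an authors' p under 0.05 were not single protein-coding genes. Non-coding models inside a locus might widen the error of its FPKM: at matched level the median absolute difference of 547 loci that join coding and non-coding genes was 1.26 times that of single coding genes in the 8rex deletion and 1.11 times in the DCC mutant, between the sizes set in advance for and against this cause, which leaves it undecided. Among the 197 such loci of the DCC mutant 20.8% were not single protein-coding genes, against 19.8% of its tests. The tables argue against a local effect of the deletions on X as the whole cause, because 38 of the 43 loci were autosomal and 63.2% of these 38 were not single protein-coding genes (exact binomial 95% interval 46% to 78.2%), against 21% of the autosomal tests. Such an effect stays open only for the 5 X-linked loci; X held 11.6% of the 43 loci (exact binomial 95% interval 3.89% to 25%) and 15.6% of the tests.

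No locus had a q under 0.05 in either comparison. The deposited q-values correspond to an adjustment over 29077 tests, of which 19233 belong to the 2 comparisons used here, and imply 23 tests at the smallest p of 5e-05, where 30 would be needed for a q under 0.05. This met the outcome set for the floor of the p-values as a cause. It was fixed once the smallest q was known to be above 0.05, so it cannot decide the question. Whether p-values free to go lower would have given a q under 0.05 is not known. Stage differences within each group may also have widened the spread that the authors' test used, but the implied standard error of 73 maternal and collagen loci in the 8rex deletion was 0.927 times that of matched loci. This met the outcome set in advance against this cause, a value at or below that of matched loci. As it also lay inside the random range of 0.897 to 1.196 and covers those loci alone, the cause is not excluded. The median p was 0.668 in the DCC mutant and 0.813 in the 8rex deletion in the authors' table. With few true differences and evenly spread p-values it would lie near 0.5, so the authors' p-values ran high. Why they did was not tested. Few true differences at this replication also stay open, but the median p does not bear on them.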

How the results depend on the processing

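The alternatives on thresholds, on single coding genes, on pseudocounts of X against autosomes, on tested loci, on all of the gene lists (matching, merged loci, filters and pseudocounts), on X by level and on 2-fold counts were added after the data were seen. No paired analysis was possible because the table holds 1 value per genotype; for the same reason leaving out replicates, the replicate block, the models without stage, on the 2 groups compared or on mixed-stage or older replicates only, other test tools, an estimated correlation of list members, the stage interaction, the comparison of older with mixed embryos, the test of the 8rex deletion against the DCC mutant gene by gene and other splits of the samples were not run.

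Counts of loci at an authors' q under 0.05 stayed at 0 in both comparisons under each filter and when adjusted over 1 comparison alone. At a q under 0.1 they were 7 in the DCC mutant and 6 in the 8rex deletion, at an unadjusted p under 0.05 197 and 43, and with single coding genes only 156 and 14; looser thresholds admit more loci by construction. Counts of 2-fold differences were 1842 (DCC mutant), 1399 (8rex deletion) and 1993 (DCC mutant against 8rex deletion) at a mean of at least 5 FPKM, 1430, 630 and 1607 at single coding genes, where fewer loci enter, and 1782 and 2000 for the DCC mutant against wild type and against the 8rex deletion with a pseudocount of 5.

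Values without a pseudocount in this paragraph are for loci above 0 FPKM in both genotypes, so the set of loci changed as well. X minus autosomes in the DCC mutant against wild type kept its direction in each alternative, at 0.43 without a filter, 0.51 at a mean of at least 5 FPKM, 0.39 with means, 0.53 and 0.37 with pseudocounts of 0.1 and 5, 0.60 at single coding genes, 0.61 without a pseudocount and 0.57 at tested loci. Against the 8rex deletion it was 0.46 without a filter, 0.31 with means, 0.58 and 0.42 with pseudocounts of 0.1 and 5, 0.63 at single coding genes, 0.65 without a pseudocount and 0.60 at tested loci. In the 8rex deletion against wild type it was -0.012 at a mean of at least 5 FPKM, 0.079 with means, -0.027 at single coding genes, -0.024 without a pseudocount and -0.031 at tested loci, so its sign was not fixed and the cause was not tested. Lists outside the random range in the 8rex deletion numbered 3 with the stricter filter and 3 without a filter, and windows of 2 Mb outside it numbered 0; the cause was not tested. In the DCC mutant 10 or 11 lists were outside under each alternative, but which lists they were differed under 4 of the 6. Of 964 alternatives for 241 fold changes of named loci, 920 moved by less than 1.5-fold and 44 by more (34 with a pseudocount of 5), the latter without a change of direction. Among the smaller moves, a value near 0 could change sign. In the DCC mutant, dpy-28 went from -0.029 to 0.009 when centred on the autosomal median. The rise of the X shift with level on the main scale, from 0.34 to 0.55, became a fall from 0.79 to 0.56 without a pseudocount, and the main scale damps low loci. Depth per library is unknown, so no floor can be given for low values.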

Other observations

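The loci in this part that the report does not name, and the windows along X in the DCC mutant, were chosen after their values were seen; each p and q given for a locus is the authors' own.

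Further genes of propionate and fatty-acid metabolism are given as values only, since no list of them was fixed or tested, and of those below hphd-1 alone had an authors' p under 0.05. The authors' deposited table gave hphd-1, a gene of the propionate shunt that shares a locus with Y38F1A.8, at 187 FPKM in wild type, 199 FPKM in the 8rex deletion and 48.8 FPKM in the DCC mutant (p = 0.00585 for the DCC mutant). The shunt gene alh-8 stood at 204, 209.7 and 120.1 FPKM in the authors' table (p = 0.372), and the loci that hold ech-6 and hach-1 at 661, 644 and 546 FPKM (p = 0.543) and at 919, 937 and 873 FPKM (p = 0.865). Of the vitamin B12 dependent enzymes, the authors' table gave mmcm-1 at 52, 54 and 41.1 FPKM (p = 0.403) and metr-1 at 37.3, 37.3 and 36.8 FPKM (p = 0.977). The desaturase gene fat-5 stood at 11.05, 11.15 and 4.89 FPKM in the authors' table (p = 0.201), and fat-7 at 0.343 and 0.580 FPKM and listed at 0. The X-linked locus of sams-1, which makes the methyl donor S-adenosylmethionine, stood at 139, 118 and 236 FPKM there (p = 0.0963 by the authors' test).

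Loci with an authors' q between 0.1 and 0.5 that the text has not named were these, in the order wild type, 8rex deletion and DCC mutant. The authors' deposited table gave F13B12.4 at 106.6, 54.3 and 23.5 FPKM (q = 0.174 in the DCC mutant), the X-linked ctsa-2/T22E5.10 at 13.2, 15 and 44 FPKM, the locus of rog-1 at 18.7, 59.5 and 51.4 FPKM, the locus of C41H7.2 at 7.07, 37.2 and 24.4 FPKM, and the locus of F58D5.5 at 187, 68.0 and 93.4 FPKM. Both mutants are compared with the same wild-type libraries, so a low or high wild-type value moves both comparisons at once.

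Along X, the window medians of the DCC mutant ran from 0.33 to 0.58. Of 18 windows of 1 Mb, 7 lay outside the range of random X-linked lists of the same size and level, and of 9 windows of 2 Mb, 4 did. If loci varied independently, 0.9 of the 18 would be expected. The random lists take loci from all along X, whereas neighbouring loci can vary together, so these counts do not show that the shift is uneven. The medians were 0.57 at 9 to 10 Mb, 0.54 at 11 to 12 Mb, 0.58 at 12 to 13 Mb and 0.56 at 13 to 14 Mb on the higher side. They were 0.33 at 3 to 4 Mb, 0.33 at 15 to 16 Mb and 0.35 at 16 to 17 Mb on the lower side. No explanation was tested.

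The ribosomal RNA locus on I (15053010 to 15071033) was listed at 0 in wild type and at 29197 and 30936 FPKM in the 8rex deletion and the DCC mutant in the authors' deposited table, with a p of 1 in both comparisons. Of the 242 rows without a gene identifier, 8 had an authors' p under 0.05 in the DCC mutant and 5 in the 8rex deletion.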
